A study of Drosophila melanogaster with 59 samples.

How the data were processed

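The deposited series holds 59 samples of Drosophila melanogaster. Long RNA (above the small RNA size range, depleted of ribosomal RNA and not selected for poly(A)) and small RNA were sequenced from adult male heads and from unfertilized eggs of 4 lines, with 2 libraries per line, tissue and RNA class. Genomic DNA of Fab2L, White* and Red* was sequenced in 27 libraries, 3 per line and crossing background, and none is listed for w1118. The 4 lines are w1118, which carries no transgene, Fab2L, which carries a transgene with the mini-white reporter, and Fab2L White* and Fab2L Red*, lines derived from Fab2L and named for their eye color. The labels do not say that the 2 libraries of a line come from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The extraction text of the egg libraries also names adult male heads, in conflict with their titles and sample descriptions. The titles were followed. The replicate numbers of the Red* egg long RNA libraries differ between titles and file labels, and the numbers of the titles were used.

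The authors deposited long RNA as FPKM per gene. STAR 2.5 and DESeq2 were used with build dm6, per the submitters' processing notes, which state neither the counting tool nor the annotation release. Small RNA was deposited by the authors as a count of reads per miRNA hairpin, with Bowtie named per the submitters' processing notes. From genomic DNA, the authors deposited lists of SNPs, small deletions and small insertions specific to Red* or to White*, made with Bowtie2, Picard and SAMtools per the submitters' processing notes. Each SNP carries genotype calls and a quality score deposited by the authors, on the caller's scale. Each small deletion carries its deposited size in bp. Each small deletion and insertion carries, for each crossing background, a deposited count of reads with the change and a deposited fraction of reads with it. The egg libraries and the libraries after 11 generations of crossing share 1 joint list of tools in the labels. The caller's settings are not stated, and why a position entered a list was not tested here.

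The test planned for long RNA was edgeR on counts. Since these values are FPKM, the fallback written with the plan was used: limma-trend on log2(FPKM + 1) for genes with FPKM above 1 in at least 2 of the 8 libraries of a tissue, with all 4 lines in 1 fit and Benjamini-Hochberg adjustment. Differences on this scale understate the fold change of genes near or below FPKM 1. The labelled lower size limit of long RNA lies above the length of tRNAs, miRNA hairpins and most snoRNAs. FPKM on such genes is therefore no measure of these small RNAs. An adjusted p below 0.05 was called in every comparison. For small RNA, edgeR's quasi-likelihood test was used on hairpin counts with TMM factors and filterByExpr, again with all 4 lines of a tissue in 1 fit. CPM of a miRNA is its count per 1 M hairpin counts scaled by the TMM factors, while shares of miRNAs and the figure use counts per 1 M without them. Every adjusted p given for a long RNA gene comes from limma, and every adjusted p given for a miRNA comes from edgeR. Tables of all genes were matched to symbols for 17252 of the 17558 gene identifiers and to dm6 positions for 17253. The lists, comparisons, tests and alternatives were fixed before the data were examined, except those stated to have been added.

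In each library, FPKM times gene length is a whole multiple of 1 step. Whole reads were worked back by taking the shortest gene length that makes all values of a gene whole within 0.001, which was found for 16144 of 16157 genes and 194775 of the 194923 values above 0. Because the length is searched for, this share alone proves little, and 2 further checks were made. The length found equalled the annotated length in 96.0% of 579 single-exon small RNA genes. When the values of 1500 genes were moved at random by about 5%, a length was still found for 44 of 50 genes with a value in 1 library, but for 1 of 51 with values in 2 and 0 of 1399 with values in 3 or more. Reads recovered for the 472 genes with a value in 1 library are therefore not secured by the search. The recovered reads gave the depth, and edgeR and DESeq2 run on them are alternatives added after the data were seen. Recovered depth was 13.5 to 36.6 M reads in heads and 27.8 to 35.6 M in eggs. miRNA counts summed to 12.0 to 20.2 M in heads and 0.270 to 1.14 M in eggs. Replicate libraries were checked for duplicates: the chi-square per degree of freedom between the 2 libraries of a line lay between 7.43 and 754, so that none is a copy or a plain resampling of the other.

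Gene lists were written beforehand from textbook knowledge: 25 lists for long RNA (Polycomb group, trithorax group, Hox genes, Polycomb targets, eye pigment, phototransduction, circadian clock, piRNA pathway, miRNA and siRNA pathway, antimicrobial, heat and humoral stress, detoxification, fat body, neuronal, glial, muscle, midgut enzymes, testis and accessory gland, olfactory, dosage compensation, maternal, early zygotic, eggshell and follicle, histone, and mitochondrial) and 5 for miRNAs (bithorax complex, head, maternal, zygotic and testis miRNAs). The w gene, on which reads of the mini-white reporter also fall, was in addition followed as a single gene. Older symbols were matched to current ones through the synonyms of the reference annotation and a short table of 12 names written after the files were seen, and the 5 replication-dependent histone classes brought all their annotated copies. Lists with at least 4 tested members entered camera with a preset correlation of 0.01, adjusted within a comparison, and were tested again with an estimated correlation. Called members were also counted with p-values adjusted over the list alone.

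The genes named per long RNA comparison are the 12 with the largest rise and the 12 with the largest fall among those called, with an average log2 value of at least 1 and no overlap between the libraries of the 2 groups. Up to 9 of each 12 carry a given name and 3 are the largest of any kind. w, Pc, E(z), ph-p and Abd-B are given in every comparison where they were tested, and up to 4 called members of a list may be named. For miRNAs the rule names 5 in each direction, and for the comparison of tissues the 5 smallest p-values. Where fewer pass, the smallest p-values are named. A gene that 2 parts of the rule name is counted once in the totals.

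The scripts were tested on simulated data drawn from the real means, depths and common dispersion for Red* against White*. In heads, limma recovered 85.9% of genes changed 2-fold (85 of 99 tested) and 99% of those changed 4-fold (99 of 100 tested). It made 19 false calls among 11037 genes. In eggs limma recovered 100% of both (87 and 90 tested) with 17 false calls among 6624 genes. In both tissues, false calls thus made up a larger share of all limma calls than the adjusted p threshold allows. edgeR on reads recovered 95% and 100% in heads and 96.9% and 99% in eggs, with 10 false calls in each. That share of the edgeR calls on reads lay just below the threshold. For miRNAs, edgeR recovered 86.7% and 100% in heads with 0 false calls, and 100% of both in eggs (11 and 12 tested) with 2 false calls. For egg miRNAs the share of false calls was also above the threshold, but rests on few calls. The comparison of tissues recovered 63.6% and 100% with 8 false calls.

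Alternatives were: quantile normalization (RLE factors for counts, and quantile normalization in place of the planned RLE for the comparison of tissues), no filter, only the 2 lines compared, a replicate block, removal of the 20 most abundant long RNAs or 5 most abundant miRNAs with the rest rescaled, pseudocounts of 0.1 and 10, DESeq2, and each library left out in turn. Each changed 1 choice, with these exceptions. The removal of long RNAs also brings every library to the same summed FPKM, so it changes the scaling too. DESeq2 on miRNA counts changes the scaling, the test and the filter together. edgeR and DESeq2 on whole reads change the input as well. They tested 11983 and 9829 genes in Red* against White* heads, against 11119. A planned DESeq2 fit of the long RNA files as deposited was not run, since they hold no counts, and pseudocounts do not apply to the miRNA counts. With 1 library left out, the lone library of that line is assumed to vary like the other lines. Chromosome arms were compared between the Red* and White* lists by permutation (1e+05 resamples). Genes within 2000 bp of a SNP were counted against circular rotations of the calls along the genome. Exonic SNPs are those in coding or untranslated positions in the location column, matched to genes by symbol. Raw reads, spliced isoforms, transposons, piRNAs and other small RNAs outside miRNA hairpins were not analysed here. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.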

Results

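Flies of 4 lines were compared to ask which transcripts differ between lines that share a transgene but not an eye color. Fab2L carries a transgene with the mini-white reporter, White* and Red* are lines derived from Fab2L, and w1118 carries no transgene. Long RNA and small RNA came from adult male heads and from unfertilized eggs, with 2 libraries per line. Genomic DNA of Fab2L, White* and Red*, crossed into Oregon-R and Canton-S backgrounds, gave lists of sequence variants specific to Red* or White*. Long RNA depth was 13.5 to 36.6 M reads per library in heads and 27.8 to 35.6 M in eggs. Head depth split by line, at 13.49 and 14.96 M in Fab2L and 16.05 and 13.8 M in White*. Red* had 25.17 and 36.6 M and w1118 31.1 and 25.59 M. Among the head comparisons only White* against Fab2L joins lines of like depth. In the others line and depth cannot be told apart. In egg small RNA, hairpin counts summed to 0.317 and 0.270 M in Fab2L and 1.14 and 0.859 M in Red*. In heads the signal recognition particle RNA 7SLRNA:CR32864 held 21.6% of the summed FPKM, and the mitochondrial transcript mt:CoI held 1.26%. In eggs the same 7SL gene held 7.28%. mir-8 (19.6%), mir-276a (14.3%) and bantam (11.1%) were the most abundant miRNAs of heads, and mir-311 (30.6%), mir-312 (22.1%) and mir-92b (14.1%) those of eggs.

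Whether the lines differ in the reporter was asked first in heads. The white gene w (X:2790599-2796466, dm6) encodes an ABC transporter subunit for eye pigment precursors, and reads of the mini-white reporter fall on the same gene. It stood at 10.8 ± 1.31 FPKM in Red* (mean ± SD, n = 2 for all values of this kind), 2.32 ± 0.0599 in White*, 5.75 ± 0.0955 in Fab2L and 0.211 ± 0.0246 in w1118, where 14 reads were recovered in each library. w was higher in Red* than in White* (log2 fold change 1.82, SE 0.11, adjusted p = 0.000863) and higher in Fab2L than in w1118 (2.48, adjusted p = 4.19e-05). It fell by 1.02 from Fab2L to White* (adjusted p = 0.0308) and rose by 0.80 from Fab2L to Red* (adjusted p = 0.0190). These last 2 calls end when any 1 of the 4 libraries compared is left out. The adjusted p for White* against Fab2L is then 0.202 and 0.211 without Fab2L replicates 1 and 2, and 0.196 and 0.252 without White* replicates 1 and 2. For Red* against Fab2L it is 0.114 and 0.116 without the Fab2L replicates, and 0.0548 and 0.0540 without the Red* replicates.

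The Polycomb group genes Pc, E(z) and ph-p encode subunits of the repressive complexes PRC1 and PRC2. In heads Pc stood at 16.7 ± 0.669 FPKM in Red* and 16.3 ± 0.754 in White* (adjusted p = 0.862). E(z) stood at 12.2 ± 0.215 and 12.1 ± 1.48 (adjusted p = 0.942), and ph-p at 9.98 ± 0.780 and 9.98 ± 1.10 (adjusted p = 0.994). The Hox gene Abd-B (3R:16927212-16972236) had 0 to 2 reads per library and was not tested. In eggs w was near the limit of detection, at 0.0248 FPKM in Red* and 0.0466 in White*.

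**Figure D1:**
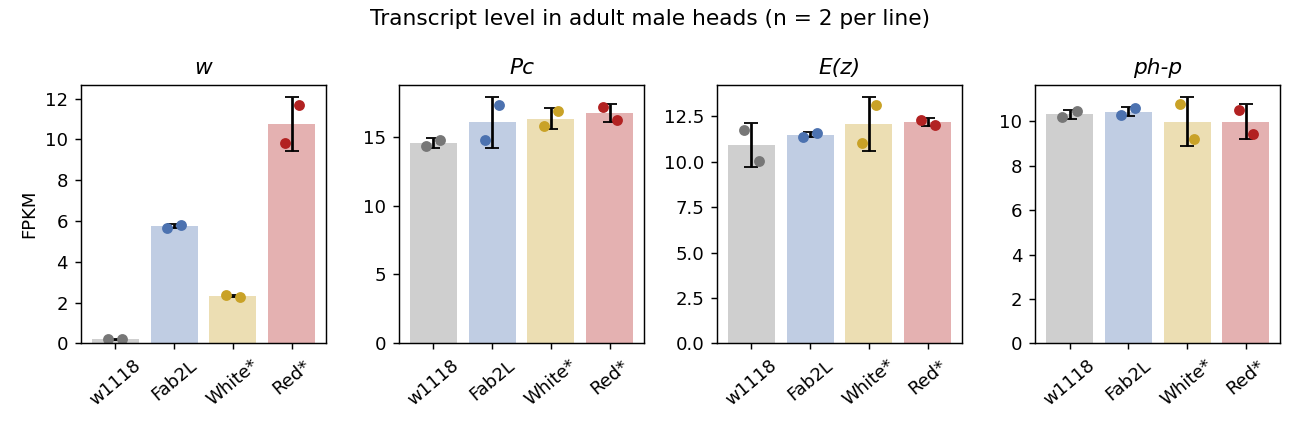
Level of w, Pc, E(z) and ph-p in adult male heads of w1118, Fab2L, White* and Red*. Bars show mean FPKM, points the 2 libraries and error bars the SD; w differs between the lines while the 3 Polycomb group genes keep similar levels.

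In heads of Red* against White*, many transcripts outside the reporter also differed. The sepia gene se, a step of red pteridine pigment synthesis, was lower in Red* (41.2 ± 1.43 against 115 ± 5.61 FPKM, log2 fold change -1.46, adjusted p = 0.00079). So were Srg1 (1.90 ± 0.0215 against 15.9 ± 3.98, -2.52, adjusted p = 0.000863), the eclosion hormone gene Eh (0.906 ± 0.493 against 8.51 ± 0.840, -2.34), Srg3 (-2.22) and Arc1, a retrotransposon-derived neuronal gene (215 ± 31.4 against 643 ± 46.3, -1.58, adjusted p = 0.0024). The odorant binding protein Obp99b (-2.04), the transcription factor Ets21C (-1.79), snRNA:U11 of the minor spliceosome (718 ± 29.8 against 2454 ± 457, -1.76), the peptidoglycan receptor PGRP-SA (-1.54) and the glutathione transferase GstD2 (5.58 against 18.4 ± 8.39) fell as well, as did lncRNA:CR45456 (-3.02), lncRNA:CR45457 (-2.69) and CG17005 (-2.64). Higher in Red* were the mucin Muc68D (28.9 ± 23.3 against 0.633 ± 0.664, 4.00), CG34324 (3.62), CG3906 (2.81), CG14329 (2.09), the chitinase Cht8 (1.38), the Methuselah-like receptor mthl8 (15.8 ± 1.72 against 6.12 ± 0.356, 1.24), mir-31b (1.16) and mir-4978 (1.13). The transfer RNAs tRNA:Lys-CTT-1-4 (1.68), tRNA:Thr-AGT-1-1 (1.54) and tRNA:Asp-GTC-1-1 (1.92, listed at 0 in White*) also rose, with reads that near-identical copies may share. Long RNA was selected above the length of tRNAs and miRNA hairpins, so these values do not measure mature miRNAs or tRNAs. In small RNA of heads neither mir-31b nor mir-4978 was called between Red* and White*. Differences on the log2(FPKM + 1) scale understate the fold of low genes.

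Of 11119 genes tested, 94 were higher and 336 lower in Red* heads (limma), and 2576 had an unadjusted p below 0.05. Leaving out 1 library leaves 1 for that line, which also lowers the power of the test. A loss of calls therefore does not show that a single library drives them. The count was lower in most of these fits. It fell to 26 without Red* replicate 1, 21 without White* replicate 1 and 25 without White* replicate 2, and Srg1, se, Arc1 and w stayed called in every one of these fits. With the 20 most abundant RNAs removed the split was 154 higher and 204 lower.

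Among 23 eye pigment genes, w rose and 5 fell in Red* heads (1 and 9 when adjusted over the list alone). Those that fell include se, the transporter subunit bw (6.79 ± 0.857 against 13.5 ± 1.25, -0.90) and pr (-0.66). se and pr act in the synthesis of pteridines. The list passed camera (adjusted p = 0.0107; adjusted p = 0.769 with an estimated correlation). Of 32 Polycomb targets 3 rose and 0 fell (5 and 1 alone): the homeobox genes hth (19.8 against 13.8 FPKM, 0.48), ey (0.43) and toy (0.38), with camera adjusted p = 0.0214 and adjusted p = 0.769 with an estimated correlation. Of 22 neuronal genes limma called 1, the GABA receptor gene Rdl (0.84), as higher, 6 were higher at unadjusted p below 0.05, and DESeq2 on whole reads called 5 (camera adjusted p = 0.00108; adjusted p = 0.769 with an estimated correlation). TotX was called as lower among 21 stress genes (-0.85; camera adjusted p = 0.0153; adjusted p = 0.769 with an estimated correlation), and His3.3A among 93 histone genes (-0.90; camera adjusted p = 0.0168; adjusted p = 0.789 with an estimated correlation). Neither His3.3A nor any other histone gene passed over the list alone. Detoxification genes gave 0 higher and 3 lower of 41, among them GstD1 (160 ± 18.3 against 262, -0.71) and Cyp6a8 (-0.92), while their median change was slightly above 0 and their mean -0.12. Leaving out Red* replicate 1, White* replicate 1 or White* replicate 2, which also lowers power, ended most eye pigment calls. The Polycomb target, neuronal, stress, histone and detoxification lists lost all their calls in these fits. Without Red* replicate 2 they gave 6 lower eye pigment genes, 2 higher Polycomb targets, 2 higher neuronal genes, and 1 higher and 1 lower detoxification gene.

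Mitochondrial transcripts (0 of 14 called, 3 higher over the list alone), muscle genes (0 of 21) and midgut enzymes (0 of 21) passed camera as higher in Red* heads, at adjusted p = 0.0214, 0.0214 and 0.0435, and each had adjusted p = 0.769 with an estimated correlation. At unadjusted p below 0.05 these lists had 4, 5 and 0 genes higher in limma, and DESeq2 on whole reads called 2, 2 and 6. Antimicrobial genes gave 2 lower of 30 (LysX, -1.21), olfactory genes 1 higher (Obp56h, 0.58) and 2 lower of 28 (Obp19c, -1.03), and phototransduction genes 2 lower of 34 (laza, -0.75; Rh6, 12.3 against 18.8, -0.58). Fat body markers and early zygotic genes had 1 lower each, of 15 and 6. These 5 lists also had 0 calls without Red* replicate 1, White* replicate 1 or White* replicate 2, and without Red* replicate 2 the antimicrobial list gave 1 higher and 1 lower, the olfactory list 1 and 4, fat body markers 3 lower and early zygotic genes 0. No member of the Polycomb group (24), trithorax group (23), circadian (16), dosage compensation (8), eggshell (4), glial (13), maternal (22), miRNA and siRNA (14), piRNA (22), testis (6) or Hox (3) lists was called by limma over all genes. Adjusted over the list alone, the miRNA and siRNA list had 2 higher and 1 lower, the testis list 2 higher and the others 0. At unadjusted p below 0.05 they had, in this order, 1, 3, 2, 1, 0, 0, 2, 2, 3, 2 and 1 genes higher and 1, 1, 1, 0, 0, 4, 0, 1, 2, 0 and 0 lower. DESeq2 called 1, 2, 0, 0, 0, 2, 1, 3, 1, 0 and 1 of them, and edgeR on whole reads 1 each in the Polycomb group and the miRNA and siRNA list.

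Next, each derived line was set against Fab2L in heads. White* differed from Fab2L in 10 higher and 3 lower genes (limma). mthl8 rose from 0.0211 ± 0.0014 to 6.12 ± 0.356 FPKM (2.80, adjusted p = 0.00133), CG7829 from 14.3 ± 1.14 to 67.7 ± 13.1 (2.16, adjusted p = 0.00133), and CG31205 (2.25), CG31174 (1.80), dpr21, an immunoglobulin domain gene (1.06), Cyp12a4 (0.75) and tRNA:Tyr-GTA-2-1 (1.44) rose too. Lower were w, snRNA:U4atac (-0.99) and snoRNA:Dek-a (-0.96). Without White* replicate 1 the count fell to 2, and without Fab2L replicate 1, Fab2L replicate 2 and White* replicate 2 it was 4, 3 and 3. The split was 9 and 5 with edgeR on whole reads and 14 and 45 with DESeq2. Antimicrobial genes (0 of 30 called, 4 lower over the list alone, camera adjusted p = 2.63e-12), mitochondrial transcripts (0 of 14, 1.37e-06), fat body markers (0 of 15, 3 lower alone, 0.000105) and detoxification genes (0 of 41, 0.0184) passed camera as lower. Their adjusted p = 0.724, 0.845, 0.237 and 0.902 with an estimated correlation, in this order. At unadjusted p below 0.05 limma had 13, 3, 6 and 5 of them lower, and DESeq2 called 5, 2, 3 and 0. Polycomb group genes gave 0 calls by every tool.

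Red* heads differed from Fab2L in 42 higher and 208 lower genes. mthl8 stood at 15.8 ± 1.72 against 0.0211 FPKM (4.04, adjusted p = 0.000134), and the kinesin gene Kif3C at 23.0 ± 0.148 against 11.3 ± 0.831 (0.96, adjusted p = 0.00617). Muc68D (3.52), CG34324 (3.22), CG3906 (3.01), CG14329 (2.28), Cht8 (1.41), the dynein heavy chain Dhc93AB (1.37), winged eye wge (22.7 ± 4.09 against 9.80 ± 0.357, 1.12) and lncRNA:noe (7258 ± 428 against 3629 ± 113) were higher. Srg1 (1.90 against 31.3 ± 2.15, -3.48, adjusted p = 0.000236), Srg3 (-2.66), CG33462 (-2.66), lncRNA:CR45456 (-2.52), the fat body gene fit (10.4 ± 4.25 against 41.4 ± 0.536, -1.94), Ets21C (-1.87), PGRP-SA (-1.77), Obp99b (-1.77), the lysozyme LysS (-1.71), Eh (-1.45) and se (-1.43, adjusted p = 0.000855) were lower. Antimicrobial genes gave 4 lower of 30 (14 alone), such as LysX (-1.29) and BaraA1 (270 against 533 ± 151 FPKM, -0.95), with camera adjusted p = 1.7e-09 and adjusted p = 0.749 with an estimated correlation. Eye pigment genes gave 1 higher and 5 lower (1 and 9 alone; 0.000204; adjusted p = 0.749 with an estimated correlation), with v (-0.65) and bw (-0.90) among the lower ones. Fat body markers gave 3 lower (7 alone; 0.000197; adjusted p = 0.246 with an estimated correlation) and detoxification genes 3 lower (8 alone; GstD5, -1.08; 0.00432; adjusted p = 0.750 with an estimated correlation). Listed as higher by camera were neuronal genes (0 of 22 called, 0.00143; 5 higher and 1 lower at unadjusted p below 0.05, 1 call by edgeR on whole reads and 3 by DESeq2), muscle genes (0 of 21, 0.00261; 2 higher, 0 and 2 calls), Polycomb targets (1 of 32, 0.00308) and trithorax group genes (0 of 23, 0.0493; 2 higher, 0 and 0 calls), with adjusted p = 0.749, 0.750, 0.750 and 0.750 with an estimated correlation. Stress genes passed as lower (TotX, -1.24; 0.0488; adjusted p = 0.882 with an estimated correlation). Antimicrobial calls came down to 2, 1 and 1 without Fab2L replicate 1, Fab2L replicate 2 and Red* replicate 2. Eye pigment genes gave 1, 1 and 2 lower without Fab2L replicate 1, Fab2L replicate 2 and Red* replicate 1, and fat body markers and detoxification genes 0, 0 and 1 each. Without Red* replicate 2 detoxification genes gave 1 higher and 1 lower. The TotX call and the Polycomb target call also ended without any 1 of these 3 libraries, and the latter without Red* replicate 2. The count fell to 43, 36 and 74 without Fab2L replicate 1, Fab2L replicate 2 and Red* replicate 1. With the 20 most abundant RNAs removed, the split was 75 and 84 and the median of all genes shifted by 0.12 log2.

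The transgenic line Fab2L and w1118 differed in 390 higher and 347 lower genes of heads. The antimicrobial peptide genes Mtk (489 ± 76.4 against 40.9 ± 3.85 FPKM, 3.54, adjusted p = 0.0200) and Def (73.6 ± 21.5 against 9.39 ± 4.08, 2.87), the cytochrome P450 Cyp6a2 (156 ± 13.6 against 16.3 ± 0.626, 3.18, adjusted p = 2.17e-05), Srg1 (3.31), Arc1 (439 ± 9.70 against 56.1 ± 3.79, 2.95) and GNBP-like3 (2.91) were higher in Fab2L. CG33462 (3.27, listed at 0 in w1118), lncRNA:CR44393 (3.12), CG5966 (3.06), snoRNA:CG32479-a (2.62) and mir-9b (2.46) were higher too. Lower in Fab2L were the odorant binding protein Obp57a (2.31 ± 0.211 against 162 ± 8.62, -5.62, adjusted p = 2.34e-05), Muc68D (1.48 against 87.7 ± 8.59, -5.35), CG34324 (-5.08), whe (-4.67), CG31808 (-4.65), CG3906 (-4.58), mthl8 (-3.78), takeout to (32.2 ± 1.03 against 466 ± 153, -3.77), snoRNA:Psi28S-1837a (-3.35), the troponin TpnC4 (-2.92), the rhodopsin Rh6 (16.6 ± 0.441 against 97.8 ± 9.76, -2.49) and Ugt37B1 (-2.41). The count was 302 and 289 without Fab2L replicates 1 and 2, and 318 without w1118 replicate 2.

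Antimicrobial genes were 12 higher and 0 lower of 30 in Fab2L heads (18 and 1 alone; camera adjusted p = 9.95e-10; adjusted p = 0.768 with an estimated correlation). Detoxification genes moved in both directions, with 10 higher and 7 lower of 41 (14 and 8 alone; Cyp6a2; Cyp4p1, 120 against 25.9 FPKM, 2.18; 0.0325; adjusted p = 0.844 with an estimated correlation). Muscle genes gave 8 lower of 21 (14 alone), such as the flight muscle actin Act88F (2.21 against 15.2 ± 4.33, -2.31), with camera adjusted p = 1.04e-06 and adjusted p = 0.768 with an estimated correlation. Midgut enzymes gave 2 lower of 21 (2 higher and 13 lower alone; gammaTry, -1.24; 6.61e-05; adjusted p = 0.844 with an estimated correlation). Phototransduction genes gave 2 higher (ninaD, 20.3 against 3.92, 2.13) and 4 lower (Rh6; trpl, 174 against 439, -1.31), fat body markers 3 higher and 3 lower (Lsp2, -1.40), eye pigment genes 3 higher, and the piRNA list 1 higher and 1 lower (piwi, 2.51 against 15.3, -2.20). The 12 antimicrobial calls came down to 6 and 2 without Fab2L replicates 1 and 2 and to 1 without each w1118 replicate. Without Fab2L replicate 1, Fab2L replicate 2 and w1118 replicate 2, in this order, detoxification genes gave 5, 4 and 6 higher and 5, 2 and 5 lower, muscle genes 1, 2 and 1 lower, midgut enzymes 0 each and phototransduction genes 1 higher and 2 lower each. Without w1118 replicate 1 midgut enzymes gave 1 higher and 5 lower and detoxification genes 11 and 3. Fat body markers gave 1 higher and 2 lower without Fab2L replicate 1 or w1118 replicate 1 and 3 and 5 without w1118 replicate 2, eye pigment genes 1 higher without Fab2L replicate 1 or w1118 replicate 2, and piwi was the only piRNA call without Fab2L replicate 2 or w1118 replicate 2.

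The miRNAs of heads were compared in the same way. Of 172 hairpins, mir-375 (1.21, adjusted p = 0.0418) and mir-969 (0.79, adjusted p = 0.0243) were higher and mir-285 (2132 ± 48.5 against 3050 ± 38.1 CPM, -0.52, adjusted p = 0.00925) and mir-282 (-0.62, adjusted p = 0.0243) lower in Red* than in White* (edgeR). These calls fell to 2 without Red* replicate 1 and to 0 without White* replicate 1 or 2, where 19 and 12 hairpins had an unadjusted p below 0.05. Against Fab2L, White* had mir-4969 higher (0.99, adjusted p = 0.0136). Red* had mir-4969 (0.68) and mir-969 (0.67) higher and mir-282 (-0.65) and mir-285 (-0.37) lower. The White* call ended without Fab2L replicate 1, Fab2L replicate 2 and White* replicate 1 (0 calls each, with 23, 5 and 5 hairpins at unadjusted p below 0.05), and the Red* calls without Fab2L replicate 1, Fab2L replicate 2 and Red* replicate 1 (0 each, with 28, 20 and 22). None of these 4 Red* calls stayed without Red* replicate 2 either, where 5 other hairpins were called. Fab2L had 7 higher and 8 lower than w1118. mir-986 stood at 3557 ± 189 against 505 ± 55.3 CPM (2.79, adjusted p = 6.44e-07), and mir-4940 (-2.83), mir-960 (-2.45) and mir-990 (87.2 ± 7.91 against 342 ± 14.0, -1.99) were lower. That count was 7 without each Fab2L replicate and 8 without w1118 replicate 1, and without w1118 replicate 2 the lower calls numbered 5. The testis miRNA list was lower in Fab2L (1 of 9 called, 4 alone; camera adjusted p = 0.0241; adjusted p = 0.225 with an estimated correlation). Of the bithorax complex miRNAs 1 of 3 fell (3 alone; 0 without any 1 of the 4 libraries), while head miRNAs gave 1 higher and 1 lower of 21 (0 without Fab2L replicate 1, Fab2L replicate 2 or w1118 replicate 1, and 1 lower without w1118 replicate 2), maternal miRNAs 1 higher of 25 and zygotic miRNAs 0 of 4 (0 at unadjusted p below 0.05 in edgeR and 0 by DESeq2).

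Unfertilized eggs hold maternal RNA, and there the question was whether Red* and White* differ before zygotic transcription. Several transcripts of adult tissues stood higher in Red* eggs. The yolk protein genes Yp2 (5.38 ± 0.448 against 0.0576 ± 0.0528 FPKM, 2.59, adjusted p = 1.84e-05) and Yp3 (5.25 ± 0.496 against 0.0757, 2.54), the rhodopsin ninaE (3R:19886255-19888206; 5.57 ± 0.227 against 1.55 ± 0.144, 1.36, adjusted p = 4.6e-05), the arrestin Arr2 (3.44 ± 0.0980 against 0.793 ± 0.110, 1.31) and fit (1.40 ± 0.0932, listed at 0 in White*) were among them. RpL22 (52.4 ± 5.74 against 14.7 ± 3.25, 1.78), sta (480 ± 1.99 against 185 ± 16.3, 1.37) and RpL8 (510 against 215 ± 37.6, 1.25), which encode ribosomal proteins, rose too, as did sncRNA:CR43603 (2.19), CG5455 (2.16), CG30428 (1.97), CG12708 (1.66) and vari (1.44). Lower in Red* eggs were the germline gene tut (42.9 ± 6.54 against 197 ± 9.94, -2.18, adjusted p = 1.93e-05), wge (3R:22710883-22721150; 1.04 ± 0.106 against 7.84 ± 0.484, -2.12, adjusted p = 4.23e-06), CG42857 (-2.16), snoRNA:Me28S-A982b (-2.04), CG4476 (-1.93), mt:ATPase6 (-1.76), snoRNA:Psi28S-3342 (-1.58), CG7460 (-1.57), the cell adhesion gene Dscam4 (-1.52) and Scp1 (-1.50).

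In all, 1437 genes were higher and 1516 lower of 6682 tested in Red* eggs (limma). The balance depends on 1 choice. With the 20 most abundant RNAs removed and the rest rescaled to an equal sum, 2904 were higher and 424 lower. The median of all genes then shifted by 0.19 log2. Quantile normalization (1442 higher and 1274 lower), edgeR on whole reads (1701 and 1467) and DESeq2 on whole reads (1402 and 1278) kept a near-even split. Directions of genes that changed little are therefore relative to whether this removal is made. Without White* replicate 2 the count was 1117 (670 higher and 447 lower), and without White* replicate 1 the lower genes numbered 981.

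Trithorax group genes moved both ways in eggs, with 7 higher and 5 lower of 21 (7 and 5 alone; camera adjusted p = 0.185; 14 and 0 with the most abundant RNAs removed). trx itself, a histone H3K4 methyltransferase gene (3R:14263358-14286903), stood at 12.4 ± 0.328 FPKM in Red* and 5.87 ± 0.0575 in White* (0.97, adjusted p = 1.93e-05). Polycomb group genes gave 5 higher and 2 lower of 22 (4 and 2 alone; camera adjusted p = 0.206; 14 and 2 with the most abundant RNAs removed). Trithorax group calls came down to 5 higher and 2 lower without White* replicate 1, 2 and 1 without White* replicate 2 and 5 and 3 without Red* replicate 2, and Polycomb group calls to 4 and 1 without White* replicate 1 and 2 and 0 without White* replicate 2. Sce (0.54) and Spps (0.38) were higher, while pho (85.9 ± 28.1 against 135 ± 7.93, -0.69) and sxc (127 against 183, -0.54) were lower. Pc stood at 13.8 ± 0.0805 and 14.6 ± 0.0242 (adjusted p = 0.367), E(z) at 38.6 ± 0.429 and 34.9 ± 3.40 (adjusted p = 0.101). Histone genes gave 1 higher and 84 lower of 113 copies in Red* eggs (camera adjusted p = 1.29e-12; adjusted p = 0.571 with an estimated correlation), with His2A:CG31618 at 3662 ± 421 against 5608 ± 114. Since copies share reads they are not separate observations. The split was 5 and 38 with quantile normalization and 2 and 38 with the most abundant RNAs removed, and the lower copies numbered 49 without Red* replicate 2 and 21 without White* replicate 2.

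piRNA pathway genes gave 3 higher and 11 lower of 31 (AGO3, -0.76; vls, 0.52; camera adjusted p = 0.0276 as lower; adjusted p = 0.571 with an estimated correlation), but 8 higher and 3 lower with the most abundant RNAs removed. Detoxification genes gave 1 higher and 8 lower of 18 (GstE7, 13.9 against 29.7 FPKM, -1.05; 0.0276; adjusted p = 0.571 with an estimated correlation), with 1 and 3 and a median above 0 after that removal. Mitochondrial transcripts gave 2 lower of 15 (0 alone; mt:srRNA, -1.25; 0.0284; adjusted p = 0.571 with an estimated correlation). Of 7 fat body markers 5 rose and 1 fell (0.0146; adjusted p = 0.498 with an estimated correlation), the 3 eggshell and follicle genes tested, all of which rose, are Yp1, Yp2 and Yp3, which are also 3 of these fat body markers, and of 9 phototransduction genes 5 rose and 2 fell (Arr1, 1.82 against 0.300, 1.12; camera adjusted p = 0.0646). Stress genes gave 6 higher and 2 lower of 11, with Hsp70Bbb (0.85), Hsp70Bc (0.83) and Hsp70Ba (0.80), copies that share reads, against Hsp23 (-1.14). Maternal genes gave 5 higher and 9 lower of 33 (pgc, -0.62; png, 0.51), but 16 and 4 with the most abundant RNAs removed. The miRNA and siRNA list gave 4 and 4 of 14 (tral, 188 against 86.7, 1.11; AGO2, 0.66; Hen1, -0.42), eye pigment genes 4 and 3 of 13, and circadian genes 3 and 0 of 6. Of the antimicrobial, early zygotic and testis lists 1 gene each was tested, and BomS2 (1.28) and slam (0.21) rose. Dosage compensation (5 tested: mof, 0.24, Sxl, -0.23), midgut (5: LManII, 0.63), glial (3), neuronal (2: unc-13 lower), muscle (2: Tm1 lower) and Polycomb target genes (2: 1 lower) gave 1 or 2 calls each, and no Hox or olfactory gene was tested. Leaving out White* replicate 2 gave the piRNA list 1 higher and 5 lower, detoxification genes 0 and 5, maternal genes 1 and 4, the miRNA and siRNA list 3 and 1, eye pigment genes 1 and 1, circadian genes 1 and 0, phototransduction genes 5 and 0, and mitochondrial, dosage compensation, glial, neuronal and muscle genes 0. Leaving out White* replicate 1 gave the piRNA list 1 and 8, detoxification genes 1 and 4, maternal genes 3 and 6, phototransduction genes 5 and 1 and mitochondrial transcripts 1 lower. Leaving out Red* replicate 2 gave detoxification genes 0 and 5, fat body markers 3 and 0, the miRNA and siRNA list 3 and 2, maternal genes 3 and 8, mitochondrial transcripts 1 lower and dosage compensation genes 0. Leaving out Red* replicate 1 gave fat body markers 3 and 0, the piRNA list 1 and 9, maternal genes 3 and 10 and mitochondrial transcripts 11 lower. The slam call stayed only without Red* replicate 1, and the Polycomb target call and the lower fat body call ended without any 1 of the 4 libraries.

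White* eggs differed from Fab2L eggs in 439 higher and 593 lower genes. The death domain gene Fadd (50.4 ± 1.22 against 19.4 ± 0.713 FPKM, 1.33, adjusted p = 1.14e-05), the spindle checkpoint gene Bub3 (38.3 against 19.6, 0.93), CG31174 (1.53), CG18731 (1.48), CG14286 (1.35), snoRNA:Psi18S-1854b (1.27) and snRNA:U5:23D (1.02) rose. CG9380 (0.184 against 19.2 ± 0.370, -4.09, adjusted p = 1.4e-07), CG30428 (-3.44), CG5455 (-2.38), Ttc19 (-1.47), Naa40 (-1.32), Yp2 (-1.29), vari (-1.08), trx (5.87 ± 0.0575 against 12.6 ± 0.0149, -0.99, adjusted p = 3.33e-05), Dus2 (-0.98), Yp3 (-0.87), otk2 (-0.83) and Polr1E (-0.69) fell. Pc was higher in White* (14.6 ± 0.0242 against 11.4 ± 1.02, 0.34, adjusted p = 0.0165), a call that ends without Fab2L replicate 2 (adjusted p = 0.0677), White* replicate 1 (adjusted p = 0.0583) or White* replicate 2 (adjusted p = 0.121). The Yp3 call ends without White* replicate 2 (adjusted p = 0.0754). All 5 tested midgut enzymes fell, such as Jon99Cii (0.0547 against 2.04, -1.52) and Jon25Biii (-1.24; camera adjusted p = 9.25e-07; adjusted p = 0.206 with an estimated correlation). The piRNA list gave 4 higher of 31, with piwi (0.26) and del (0.32; 0.0301; adjusted p = 0.595 with an estimated correlation), and 0 with the most abundant RNAs removed. Trithorax group genes gave 2 higher and 5 lower of 21, Polycomb group genes 1 and 2 of 22, and histone copies 1 and 24 of 113, or 22 and 27 with quantile normalization. The 5 midgut enzymes stayed lower whichever library was left out. Without Fab2L replicate 1, Fab2L replicate 2, White* replicate 1 and White* replicate 2, in this order, the piRNA list gave 1, 0, 1 and 0 higher, trithorax group genes 1, 1, 2 and 1 lower and 0 higher, Polycomb group genes 1, 0, 0 and 0 higher and 0 lower, and histone copies 0, 0, 1 and 0 lower and 0 higher. The count was 219 and 196 without Fab2L replicates 1 and 2, and 491 and 65 without White* replicates 1 and 2. With the most abundant RNAs removed the split was 170 and 555.

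Red* eggs differed from Fab2L eggs in 843 higher and 743 lower genes. ninaE (5.57 ± 0.227 against 0.777 ± 0.0216 FPKM, 1.89, adjusted p = 1.88e-05), Arr2 (1.53), Yp3 (1.66), Yp2 (5.38 against 1.59, 1.30), sta (1.78), RpLP0 (384 against 162, 1.25), RpS2 (1.23), Cadps (1.22), RpL22 (1.18) and sncRNA:CR43603 (2.56) were higher. wge (1.04 against 8.49, -2.22), tut (42.9 against 181, -2.06), Dscam4 (-1.47), Ugt50B3 (-1.12), the small heat shock gene Hsp23 (-1.11), Dhc98D (-0.96), CG9380 (-3.91), CG7460 (-1.79) and CG4476 (-1.70) were lower. Pc (0.26, adjusted p = 0.0223) and E(z) (38.6 ± 0.429 against 32.5 ± 0.0295, 0.24, adjusted p = 0.0339) were slightly higher. The Pc call ends without Fab2L replicate 2 (adjusted p = 0.106) or Red* replicate 2 (adjusted p = 0.0806). The E(z) call ends without Fab2L replicate 1 or 2 (adjusted p = 0.103 and 0.121) and without Red* replicate 1 or 2 (adjusted p = 0.0588 and 0.107). In limma 5 Polycomb group genes rose and 0 fell of 22 (6 and 0 alone; camera adjusted p = 0.127; 10 and 0 with the most abundant RNAs removed). They came down to 0 without Fab2L replicate 2 and 1 higher without Red* replicate 2, and gave 3 higher and 2 lower without Red* replicate 1. Fat body markers gave 5 higher of 7 (0.000896; adjusted p = 0.250 with an estimated correlation), midgut enzymes 4 lower of 5 (0.00151; adjusted p = 0.366 with an estimated correlation), stress genes 6 higher and 2 lower of 11 (0.0331; adjusted p = 0.592 with an estimated correlation) and phototransduction genes 4 higher and 1 lower of 9 (0.0358; adjusted p = 0.592 with an estimated correlation). Detoxification genes gave 1 higher and 5 lower of 18 (0.0358; adjusted p = 0.670 with an estimated correlation), but 4 and 3 with the most abundant RNAs removed. Mitochondrial transcripts had 0 of 15 called by limma (2 lower at unadjusted p below 0.05, 1 call by edgeR on whole reads and 0 by DESeq2), with camera adjusted p = 0.0303 as lower and adjusted p = 0.670 with an estimated correlation. Histone copies gave 65 lower of 113 (75 alone; 1.84e-17; adjusted p = 0.583 with an estimated correlation), 33 with quantile normalization, and 8 and 0 without Fab2L replicates 1 and 2. Fat body calls came down to 2 and 3 without Red* replicates 1 and 2, phototransduction calls to 3 higher without Fab2L replicate 1, Fab2L replicate 2 or Red* replicate 2, and detoxification calls to 3 lower without Fab2L replicate 2. The higher detoxification call ended and 1 stress gene was called as lower without Fab2L replicate 1, Fab2L replicate 2 or Red* replicate 2. Without Red* replicate 1 histone copies gave 2 higher and 76 lower and phototransduction genes 3 and 2. The count fell to 722 and 348 without Fab2L replicates 1 and 2 and to 632 without Red* replicate 2. The split was 2055 and 223 with the most abundant RNAs removed, where the median of all genes shifted by 0.14 log2.

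Fab2L and w1118 eggs differed in 978 higher and 965 lower genes. CG4570 (318 ± 17.0 against 18.5 ± 1.29 FPKM, 4.03, adjusted p = 7.92e-08), His3:CG33827 and 4 further His3 copies (684 ± 20.9 against 82.0 ± 1.74, 3.05), His1:CG33855 (833 against 106, 2.96), Rdh1 (2.67), CG9380 (2.67), CG30108 (2.51) and Arc1 (7.04 against 0.576, 2.35) were higher in Fab2L. CG12560 (0.188 against 40.3, -5.12), CG30054 (-3.53), GILT3 (3.13 against 39.8, -3.31), CG12519 (-3.31), sncRNA:CR43603 (-3.23), narya (-3.04), RpS10a (-2.81), Ugt36E1 (-2.75), Drep1 (-2.60), Uhg5 (-2.33), mRpS28 (-2.29) and His2B:CG33868 (-2.20) were lower. Of the phototransduction genes, ninaE was lower in Fab2L at 0.777 against 6.63 ± 0.603 FPKM (-2.10) and Arr2 at 0.535 against 2.46 (-1.17), while Yp2 (0.61) and Yp3 (0.48) were higher. Pc (-0.25, adjusted p = 0.0204) was lower and E(z) (0.24, adjusted p = 0.0259) higher. The Yp2 call ends without w1118 replicate 1 (adjusted p = 0.0596), and the Yp3 call without Fab2L replicate 2 (adjusted p = 0.121), w1118 replicate 1 (adjusted p = 0.124) or w1118 replicate 2 (adjusted p = 0.0694). Leaving out these same libraries ends the Pc call (adjusted p = 0.113, 0.115 and 0.0509). The E(z) call ends without Fab2L replicate 1 or 2 (adjusted p = 0.0885 and 0.104) and without w1118 replicate 1 or 2 (adjusted p = 0.0842 and 0.108). No list passed camera: histone copies gave 40 higher and 29 lower of 113 (adjusted p = 0.322), detoxification genes 7 and 3 of 18 (0.177) and phototransduction genes 1 and 4 of 9 (0.159; adjusted p = 0.944 with an estimated correlation). Detoxification genes gave 4 higher and 2 lower without w1118 replicate 1 and 4 and 3 without Fab2L replicate 2, and the higher phototransduction call ended without any 1 of the 4 libraries. The count was 1165 without Fab2L replicate 2 and 1113 without w1118 replicate 1, the higher genes numbered 650 without w1118 replicate 2, and the split was 1248 and 579 with the most abundant RNAs removed.

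miRNAs of eggs differed strongly between the lines. mir-133 stood at 1164 ± 716 CPM in Red* and 82.8 ± 1.05 in White* eggs (3.66, adjusted p = 2.22e-07), with mir-210 (51.5 ± 25.8 against 3.46 ± 0.741, 3.69), the neuronal mir-124 (3.44), mir-987 (3.18) and mir-993 (2.74) higher as well and mir-982 (-2.35), mir-1013 (-1.32), mir-79 (-1.28), mir-1010 (-1.11) and mir-998 (-0.81) lower. Some of these folds rest on few reads. mir-982 had 3 and 1 reads in Red*, 7 and 6 in White*, 10 and 12 in Fab2L and 1 and 2 in w1118. In White*, mir-210 had 2 and 2 reads and mir-124 had 2 and 1. Of 76 hairpins 29 were higher and 22 lower (edgeR). Head miRNAs gave 14 higher of 15 (camera adjusted p = 1.59e-06; adjusted p = 0.00943 with an estimated correlation), and maternal miRNAs 13 lower of 23 (2.13e-05; adjusted p = 0.0227 with an estimated correlation). The maternal calls were 8 with RLE factors, 7 with DESeq2 and 2 with the 5 most abundant miRNAs removed. Leaving out White* replicates 1 and 2 gave 7 and 3 lower, and leaving out Red* replicate 1 gave 4 higher and 10 lower. The bithorax complex miRNAs gave 2 higher, the testis list 1 lower of 1 (0 without any 1 of the 4 libraries) and the zygotic list 0 of 2 (0 at unadjusted p below 0.05 in edgeR and 0 by DESeq2). The count was 34 and 30 without White* replicates 1 and 2, with 24 and 25 higher and only 10 and 5 lower. The split was 30 and 6 with the most abundant miRNAs removed, 29 and 14 with RLE factors and 28 and 11 with DESeq2, where the median of all hairpins shifted by 0.26, 0.12 and 0.12 log2.

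**Figure D2:**
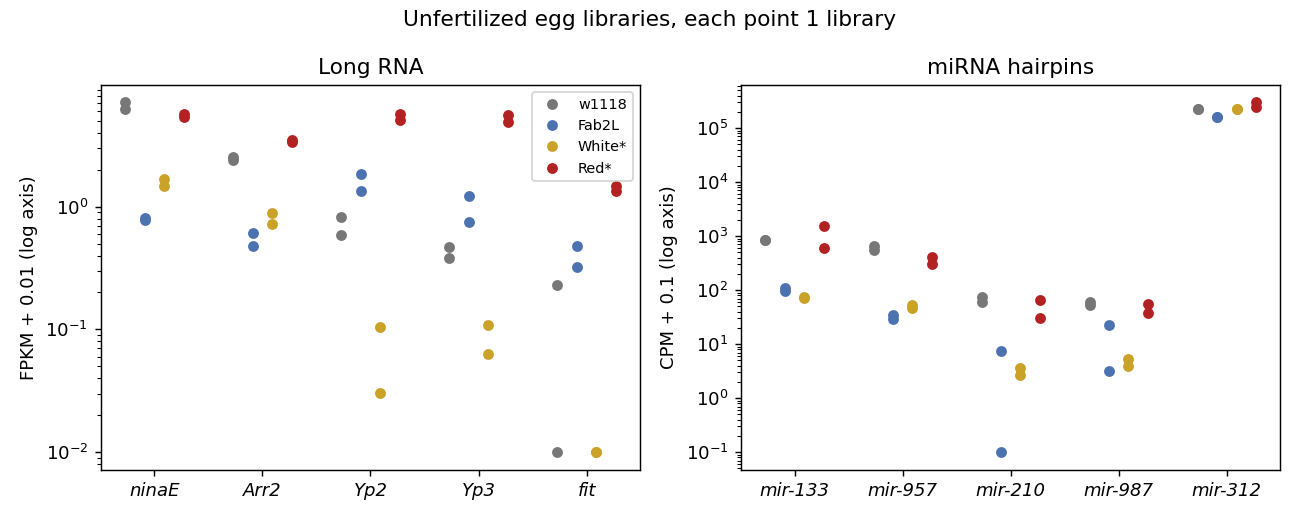
Adult-tissue transcripts and miRNAs in egg libraries, on log axes, with FPKM + 0.01 for ninaE, Arr2, Yp2, Yp3 and fit and, for 5 miRNAs, counts per 1 M hairpin counts + 0.1, without the TMM factors used for CPM elsewhere. Each point is 1 library; Red* libraries lie above White* libraries for the 5 transcripts.

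In eggs of White* against Fab2L, mir-312 (253800 ± 421 against 140600 ± 10560 CPM, 0.91, adjusted p = 5.32e-06), mir-965 (1.08), mir-957 (1.08), mir-998 (0.83) and mir-184 (0.72) rose, and mir-958 (-2.29), mir-9a (-2.20), mir-31a (-1.47), mir-34 (-1.14) and let-7 (-1.04) fell, among 12 higher and 10 lower. Maternal miRNAs gave 6 higher (0.0111; adjusted p = 0.156 with an estimated correlation), but 3 higher and 2 lower with RLE factors. They gave 3 higher without White* replicate 1, but 3 lower without White* replicate 2 and 4 lower without Fab2L replicate 2, with 0 higher in both. The split was 0 and 17 with the 5 most abundant miRNAs removed, 3 and 17 with RLE factors and 5 and 14 with DESeq2, where the median shifted by -0.26, -0.24 and -0.23 log2. The split was 7 and 4 without Fab2L replicate 1 and 4 and 3 without White* replicate 1. The 12 higher calls did not hold without Fab2L replicate 2 or White* replicate 2. With all libraries kept, most of them were also lost with RLE factors or DESeq2, and all with the 5 most abundant miRNAs removed. Their loss in the smaller fits therefore does not show that they rest on single libraries. Red* against Fab2L gave 29 higher, with mir-957 (384 ± 75.2 against 28.1 ± 4.61, 3.69), mir-210 (3.92), mir-133 (3.62) and mir-981 (3.40), and 13 lower, with mir-982 (-3.85), mir-1010 (-0.99) and mir-308 (-0.86). Without Red* replicate 1 the split was 26 and 27. mir-285 was listed at 0 in Fab2L, so that its fold has no bound. In Fab2L mir-210 had 0 and 2 reads, mir-981 had 4 and 0, and mir-315 had 1 and 1. Head miRNAs gave 12 higher of 15 (3.67e-05; adjusted p = 0.0169 with an estimated correlation), and maternal miRNAs 3 higher and 5 lower of 23 (0.00443 as lower; adjusted p = 0.0791 with an estimated correlation), or 2 and 14 without Red* replicate 1 and 6 and 7 without Red* replicate 2. Fab2L against w1118 gave 15 higher, with mir-986 (1867 ± 87.2 against 95.6 ± 28.4, 4.16, adjusted p = 2.35e-11), mir-982 (3.23) and mir-958 (1.84), and 34 lower, with mir-286 (63.9 ± 1.74 against 1924 ± 282, -5.04), mir-981 (-4.65), mir-315 (-4.59) and mir-957 (-4.45). There head miRNAs gave 13 lower of 15 (0.00116; adjusted p = 0.0385 with an estimated correlation). The split was 21 and 29 with RLE factors and 20 and 27 with DESeq2, with median shifts of 0.19 and 0.21 log2. Without Fab2L replicate 2 it was 18 and 20, and without w1118 replicate 1 it was 8 and 31.

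Variants specific to a line were mapped to ask where the derived lines differ in sequence. The 168 Red*-specific SNPs lie on 3L (142), 3R (25) and 2L (1), with 83 in the first 1 Mb of 3L and 21 between 8 and 9 Mb of 3R. The 2379 White*-specific SNPs lie on 3R (2377) and 3L (2), mostly from 25 to 31 Mb of 3R, where 1 Mb windows hold 493, 616, 418, 383, 345 and 119. The lists differ between arms (permutation p = 1e-05 for SNPs and for small deletions, the smallest possible value, and permutation p = 0.0264 for small insertions). The permutation moves each position by itself, although the White* SNPs form 774 clusters within 1 kb and mostly lie in 1 stretch of 3R. Neighbouring SNPs may be inherited together, so the p-value for SNPs overstates the number of separate observations. Transitions made up 54.8% of Red* SNPs (Wilson 95% interval 47.2 to 62.1%) and 54.3% of White* SNPs (52.3 to 56.3%). Most calls were heterozygous (167 of 168 and 2327 of 2379). Each DNA extract came from many flies, so such a call can stand for a position mixed among flies and does not give the genotype of single flies. Coding positions numbered 23 in Red* (4 nonsynonymous) and 374 in White* (105 nonsynonymous and 1 nonsense). No SNP lay on X, which carries w and ph-p. Small deletions (5 Red* and 6 White*) and small insertions (3 Red* and 1 White*) did lie there. The first of these White* deletions is at X:2497597, between ph-p and w. The nearest SNP to Abd-B was 968 kb away in Red* and 1489 kb in White*, and the nearest to E(z) 91.9 kb and 461 kb. Within 2 kb of a Red* SNP lie the list members LysB, LysE, gnu, osk, pum and Sox21b, and of a White* SNP Pdf, His2Av, Tl, pll, spz and Obp99c. Small deletions numbered 22 in Red* and 30 in White* (median 3 bp, up to 10 and 113 bp), and small insertions 20 and 16.

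**Figure D3:**
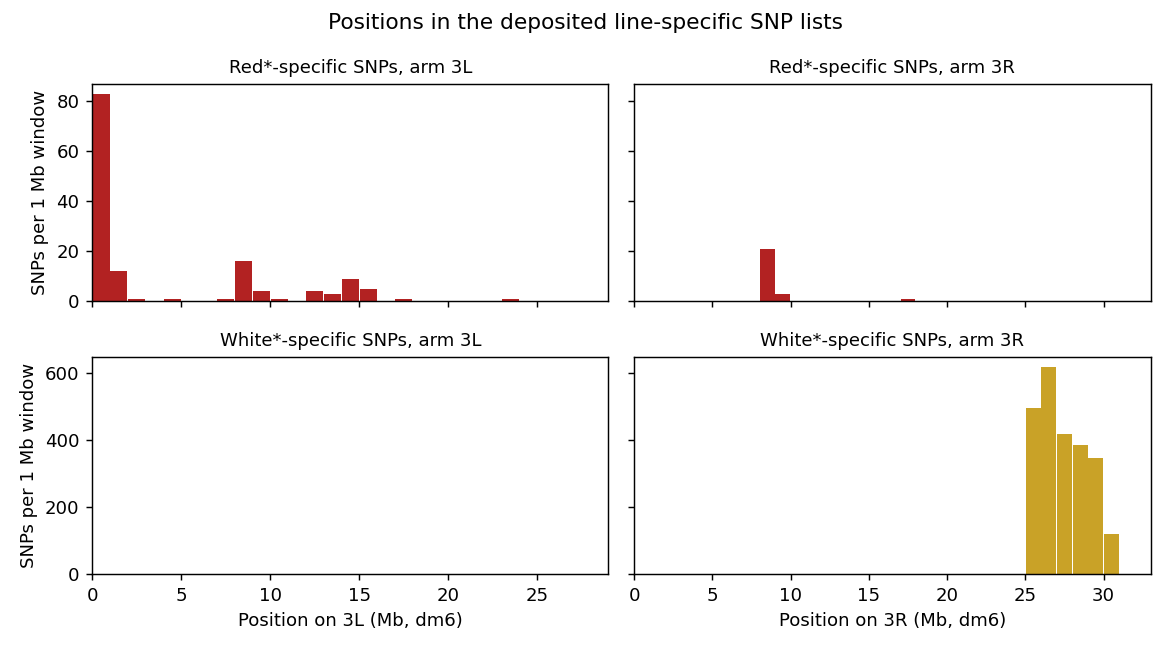
Number of Red*-specific and White*-specific SNPs per 1 Mb window along 3L and 3R (dm6). Red* positions gather at the start of 3L and White* positions near the end of 3R.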

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

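The test behind these results, of whether the Red* and White* difference itself differs between heads and eggs, was fixed before the data were seen, and only the split by the tissue a gene was tested in was chosen after the result was seen. The test called 2878 genes (limma, 1178 with a higher Red* minus White* value in heads and 1700 with a higher one in eggs), but 1815 (599 and 1216) without Red* egg replicate 2 and 1555 (463 and 1092) without White* egg replicate 2, and without White* egg replicate 1 the genes higher in heads numbered 733. Of the 2878, 2196 were tested in both tissues, 624 in heads only and 58 in eggs only. For genes tested in 1 tissue only, with little RNA in the other, the test mostly restates the difference in that tissue. The 5 genes with the smallest p-values are given as the change in heads minus the change in eggs. CG33346 had -2.67 (-2.67 in heads, not tested in eggs) and is such a gene. CG5455 had -2.48 (-0.32 in heads and 2.16 in eggs), Tollo -2.14 (-0.01 and 2.14) and vari -1.81 (-0.37 and 1.44). wge, which lies on 3R, had 3.16 (1.05 in heads, adjusted p = 0.0281, and -2.12 in eggs).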

How the results depend on the processing

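Several limits apply to these comparisons. Of 6328 alternative results for 505 named gene results, 5118 stayed the same, 1204 lost their call, 5 gained one and 1 reversed: Hsp83 in eggs of Fab2L against w1118 turned to 0.45 with quantile normalization. Leaving out 1 library accounted for 726 of the 1204. The cause of these losses was not tested. Only 2 libraries stand for each line, and the labels give replicate numbers that may be shared by number alone. With a replicate block the counts in heads were 250 (Red* against White*), 5 (White* against Fab2L), 27 higher and 98 lower, about 1.3e+02 in all (Red* against Fab2L) and 603 (Fab2L against w1118). Correlations between the deviations of libraries with the same number ran from -0.200 to 0.364 in egg long RNA and from -0.181 to 0.235 in head long RNA. edgeR and DESeq2 on whole reads were chosen after seeing the data.

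In heads of Red* against White*, the count was 165 with no filter, 156 with only 2 groups, 668 with edgeR on whole reads and 884 with DESeq2 on whole reads. For White* against Fab2L it was 59 with DESeq2. For Red* against Fab2L it was 135 with no filter, 101 with only 2 groups, 159 with the most abundant RNAs removed and 642 with DESeq2, and for Fab2L against w1118 476 with only 2 groups. In eggs it was 597 for White* against Fab2L with no filter, and 721 for Red* against Fab2L with only 2 groups. In small RNA of heads, only 2 groups gave 1 call for Red* against White*. For White* against Fab2L DESeq2 gave 3 and no filter 2. For Red* against Fab2L DESeq2 gave 14, no filter 13 and only 2 groups 1, which kept neither any of the 4 named Red* calls nor mir-4969 in White*, and for Fab2L against w1118 they gave 30, 29 and 9. With an estimated correlation 4 of 180 list tests passed, against 46 with the preset one.

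With 1 library left out, counts ran in heads from 21 to 589 (Red* against White*), 2 to 4 (White* against Fab2L), 36 to 354 (Red* against Fab2L) and 289 to 562 (Fab2L against w1118). In eggs they ran from 1117 to 2685, 65 to 491, 348 to 1655 and 1113 to 1458, in this order. For head miRNAs they ran from 0 to 6, 0 to 1, 0 to 5 and 7 to 10, and for egg miRNAs from 30 to 53 (Red* against White*) and 7 to 18 (White* against Fab2L). The count of the comparison of tissues ran from 1555 to 3293.

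Positions at or above a list's own median keep about 50% by construction, so these counts test no dependence on processing. Positions at or above the median quality numbered 89 of the Red*-specific and 1205 of the White*-specific SNPs, and White* SNPs formed 774 clusters within 1 kb. Positions at or above the median allele share numbered 11 Red* and 15 White* deletions, and 10 Red* and 8 White* insertions. Small deletions rest on a median of 2 to 5.5 reads with the change per crossing background, and small insertions on 15.5 to 51.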

Other observations

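Of the tests given here, those on lower genes within 2 kb of a SNP, on head RNA in the small RNA libraries and on copies that differ in sequence were written before their result was seen, and the other 6 tests were chosen only after the result was seen.

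Head miRNAs and 5 of 9 phototransduction genes, among them ninaE and Arr2, were higher in Red* than in White* eggs. Of the 9, 2 were lower, and that list did not pass camera (adjusted p = 0.0646, and adjusted p = 0.571 with an estimated correlation). High levels were not particular to Red*, since w1118 eggs also stood above Fab2L eggs. The median log2 change of head miRNAs was 2.23 from Fab2L to Red* and -2.46 from w1118 to Fab2L. ninaE changed by 1.89 and -2.10. Red* and w1118 eggs were not compared directly. RNA of adult tissue among the eggs may account for part of the rise in Red*. The share of adult head RNA needed to bring the rise was a median 0.0473% for 6 photoreceptor genes. These were picked as abundant in heads and low in White* and Fab2L eggs. For 50 other abundant head genes, picked as low in the same eggs, it was a median 0.0524%, a ratio of 1.11. Their shares ran from -0.0488% (Jhbp13) to 0.301% (CG2233), and some rest on few reads, such as Nplp3 with 1 in each Red* library. The like medians thus do not show that 1 share covers all these genes. Of head-abundant miRNAs 77.3% lay within 3-fold of a median share of 0.972% (range 0.0676 to 6.92%), 20.5 times the long RNA share. The miRNA share is relative to hairpin totals, which were 1.141 and 0.859 M in Red* eggs against 16.44 and 19.18 M in Red* heads. Whether 1 share covers both classes of RNA therefore cannot be told from this ratio. Carry-over from the male head libraries is argued against but not excluded, since roX1 and roX2 gave only 0.0703 of the share of long RNA. Of the 50 other abundant head genes, 45 had a share above that of roX1 (0.00632%). Shares as low as that of roX1 thus also occur among ordinary head genes. Adult female tissue stays open, since the yolk protein transcripts rose 8158 times more than male head RNA could bring, but ninaE and the yolk transcripts move apart elsewhere: from w1118 to Fab2L eggs ninaE changed by -2.10, while Yp2 (0.61, and 0.51 without w1118 replicate 1, where its call ends) and Yp3 (0.48, and 0.30, 0.44 and 0.52 without Fab2L replicate 2, w1118 replicate 1 and w1118 replicate 2, where its call ends) did not fall. Regulated loading of these RNAs into eggs remains an untested hypothesis, and staining or sequencing of single washed eggs would test it.

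Genes near Red*-specific SNPs were called in Red* against Fab2L eggs at 21 of 52 against 1532 of 6468 others (Fisher adjusted p = 0.0433). Rotation gave permutation p = 0.0249 there, and 0.1325 once adjusted. Genes near White*-specific SNPs were called more often in White* against Fab2L than other genes. They numbered 38 of 118 against 967 of 6402 in eggs and 3 of 211 against 10 of 10661 in heads (Fisher adjusted p = 6.2e-05 and adjusted p = 0.0143). A sequence block carried by the White* line and chance along the chromosome cannot be told apart, because rotating the calls along the genome gave p = 0.0089 in eggs and p = 0.00451 in heads, and p = 0.0712 for each once adjusted over 16 pairs (permutation). In Red* against White* such an excess, which a block would also bring, was not seen in eggs, at 52 of 118 against 2836 of 6402 (permutation p = 0.463 by rotation), and in heads it was 13 of 211 against 405 of 10661 (permutation p = 0.113 by rotation). Loss of reads at variant positions stays open too: 55.3% of the called genes near such a SNP were lower in White* eggs (21 of 38, Wilson 95% interval 39.7 to 69.9%, or 21 of 29 with the most abundant RNAs removed), 12 of these 38 had no such SNP in an exon, and of the 26 that had 61.5% were lower (16 of 26, Wilson 95% interval 42.5 to 77.6%, or 15 of 19). The rule written beforehand counted a share as low as this 55.3% against loss of reads. That rule named neither the Wilson interval nor the fit with the most abundant RNAs removed, and with both the question stays undecided in eggs. In heads the 3 called genes near a White*-specific SNP were all higher in White*, a direction that loss of reads would not bring. Crossing the block away and sequencing eggs again could test whether the block matters.

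Between Fab2L and w1118 eggs 5 His3 copies were higher, which might reflect copies that differ in sequence between the lines. A change of all H3 transcripts alike is argued against as the only cause, since 18 other His3 copies fell (median -0.70) while these rose (median 3.05), although copies share reads, so that these are 2 sets and not 23 observations. Summed FPKM of all His3 copies also fell, from 28740 ± 491 in w1118 to 20850 ± 453 in Fab2L, so a lower total beside the shift stays open. In heads the log2 change of the same copies exceeded that of the other copies by 1.14, but at low levels (1.09 FPKM in Fab2L and 0.170 in w1118, against 2.09 and 2.82 for the others, with a sum over all copies of 43.1 ± 23.9 in Fab2L). Reads cannot be placed with certainty among near-identical copies, and long reads of the histone cluster would test it.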
